A study of Mus musculus with 6 samples.

How the data were processed

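Total RNA from the inguinal white adipose tissue (iWAT, the subcutaneous fat pad of the groin) of aged mice kept in the cold for 7 days was sequenced in 6 libraries, 3 from vehicle-treated and 3 from estrogen-treated animals, per the labels. The authors deposited raw read counts per gene, not normalized, in a table of 54532 Ensembl genes with symbols, coordinates and gene lengths. The alignment used HISAT2 and the counting featureCounts on the mm10 genome build, per the submitters' processing notes. Their versions, the strand setting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. Genes with near-identical copies or overlapping neighbours are therefore uncertain in their counts. Of the gene identifiers, 54495 matched the mouse annotation used here (GENCODE M21, on the same build), and 53585 had the same start and end. In 27 rows a symbol had been turned into a date by spreadsheet software, and these symbols were restored through the gene identifier.

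Groups and replicate numbers were taken from the sample titles, and the column numbers of the deposited table differ from them. The labels do not say that each library came from a separate animal, so p-values measure the spread between these samples, which may in part be technical. No pair of libraries within a group agreed within sampling noise, as the chi-square per degree of freedom over genes with at least 10 counts lay between 41.7 and 88.6. Total counts were 19102059, 19014779 and 20736771 for vehicle replicates 1, 2 and 3 and 19263623, 16046601 and 16473388 for estrogen replicates 1, 2 and 3. A count of 3, taken as the detection floor, equals 0.145 to 0.187 CPM (counts scaled to a common library total) at these depths, before TMM scaling.

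Counts were scaled with trimmed mean of M values (TMM) factors and filtered with the default settings of filterByExpr, which kept 15591 genes. The 26939 genes with no count in any library carried no information. Estrogen was compared with vehicle by edgeR's quasi-likelihood F test, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05, without a replicate block. Log2 fold changes are estrogen over vehicle, their standard errors come from the F statistic, and CPM values are TMM-scaled. Gene lists were tested with limma's camera on voom values, two-sided, with a preset inter-gene correlation of 0.01 and adjustment over the 38 of 41 lists with at least 5 tested members. Camera compares a list with the other genes. Camera with an estimated correlation for each list and fry, which asks whether a list moves on balance one way, were alternatives. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

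The comparison, the tests, the gene lists, the rule for named genes and most of the alternatives were set before the data were examined. The rule named up to 10 genes per direction past the threshold with a mean log2 CPM of at least 1, a symbol that is not a predicted model, and all estrogen libraries on the same side of all vehicle libraries. Where none passed, it named the 5 genes per direction with the smallest unadjusted p, and the other criteria were kept for these. It further named a fixed set of thermogenic, adipocyte, estrogen-responsive and stress genes whatever their values, and up to 4 members with the smallest p in each list described. A few genes that the rule or the results would name are not reported here. Counts of list members past 0.05 are also given adjusted over the list alone.

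The gene test was tested in 10 simulations, each of 3 against 3 libraries over 15331 genes. Each gene had the mean and estimated spread of the real one and was drawn independently of the other genes. An earlier single simulation was replaced by these 10 because its share of false calls was imprecise. The test recovered 0.896% of genes changed 1.5-fold, 22.2% of those changed 2-fold and 82.6% of those changed 4-fold. The changed genes all had a mean log2 CPM of at least 1, and correlation between genes was left out. These shares may therefore not hold for the real libraries. Of the test's 761 calls, 61 (8.02%) were false, above the nominal share. With no gene changed, 1 of 15336 genes was called. Alternatives covered scaling, the low-count filter, DESeq2, limma-voom, a fold threshold, a looser threshold, a replicate block and leaving out each library in turn. Robust dispersions, library quality weights and leaving out both estrogen replicates 1 and 3 were added after seeing the data. GC content and length of each gene's longest transcript came from the same annotation.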

Results

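Gene expression was measured by RNA sequencing in the iWAT of aged mice after 7 days of cold, a stimulus that induces beige adipocytes, which are heat-producing fat cells within white fat. The series contrasts 3 vehicle libraries with 3 libraries from estrogen-treated mice and asks how estrogen acts on beige adipocytes of old animals. Total counts ran from 16046601 to 20736771 per library. The 20 most abundant genes took 20.7, 19.2 and 18.6% of the counts in vehicle replicates 1 to 3 and 23.4, 24.3 and 28.1% in estrogen replicates 1 to 3. Log2 CPM values correlated across genes with r of 0.972 to 0.978 within the vehicle group and 0.944 to 0.959 within the estrogen group, and 0.907 to 0.974 between the groups. Genes are not independent replicates.

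With estrogen, lipid synthesis and mitochondrial gene lists lay higher, and lists of matrix, macrophage, progenitor and endoplasmic reticulum chaperone genes lay lower. These list calls were lost with an estimated correlation (smallest adjusted p = 0.47 with an estimated correlation). Among single genes, Oxtr, the oxytocin receptor, was at 27.1 ± 0.756 CPM with estrogen and 8.44 ± 2.17 CPM with vehicle (SD, n = 3), a log2 fold change of 1.68 ± 0.21 (SE; ENSMUSG00000049112, chromosome 6, 112473683 to 112489943, mm10). Banp was at 6.90 ± 0.258 CPM against 16.8 ± 0.341 CPM, a log2 fold change of -1.28 ± 0.14 (ENSMUSG00000025316, chromosome 8, 121949750 to 122029258). Ctgf, which encodes a matrix-associated growth factor, was at 9.49 ± 0.646 CPM against 36.3 ± 12.3 CPM. None of these passed the test (edgeR quasi-likelihood, adjusted p = 0.207 for each). The other genes of smallest p were Als2cl (log2 fold change 1.02), Acsm3 (0.90), Marc1 (1.43) and Casz1 (1.27) on the higher side, and Rpl7a (-0.996), Nfxl1 (-0.85) and Tceal8 (-0.77) on the lower side. Rpl7a shares sequence with pseudogenes and its count is uncertain, and the symbol of Marc1 was restored from a date. DESeq2 called each of these 10 genes, with adjusted p from 5.99e-09 for Banp and 1.89e-08 for Oxtr to 0.00160 for Tceal8.

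By edgeR, 0 genes were higher and 0 lower past the threshold, while 3185 of 15591 genes (20.4%) had an unadjusted p under 0.05, 1480 higher and 1705 lower, where 780 would be expected by chance. This number was 1459 without vehicle replicate 2, 2358 without estrogen replicate 3, 2550 without vehicle replicate 3 and 2693 without vehicle replicate 1. DESeq2 on the same counts called 384 genes higher and 460 lower. The groups did not overlap for 4286 genes (27.5%), against 10% by chance for 3 against 3. Without estrogen replicate 2, edgeR called 13 genes higher, among them the B cell genes Cd22, Ms4a1 and Pax5, named after their values were seen. The camera test called 22 of 38 lists, 13 up and 9 down. With an estimated correlation 0 were called (smallest adjusted p = 0.47), and fry called 0 (smallest adjusted p = 0.0983), with 10 lists at an unadjusted p under 0.05. The same camera test also called 11 to 20 lists in each of the other 9 ways of splitting the 6 libraries into 3 and 3, and with 3 against 3 no such count of splits can reach a share under 0.05.

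**Figure D1:**
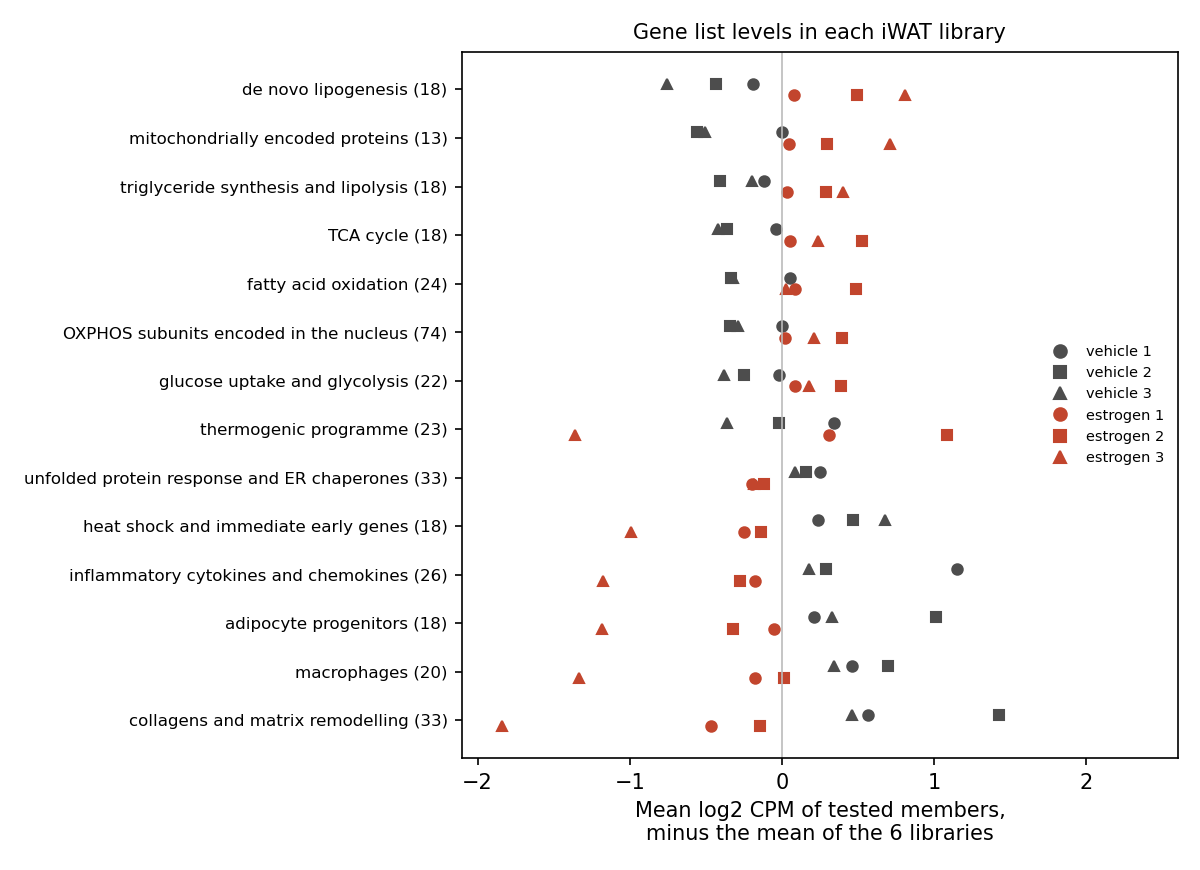
Level of 14 gene lists in each library, as the mean log2 CPM of the tested members (their number in parentheses) minus the mean of the 6 libraries, with vehicle in grey, estrogen in red and the replicate by symbol. De novo lipogenesis and TCA cycle lie higher in each estrogen library than in each vehicle library, the collagen list lies lower, and the thermogenic list overlaps.

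Genes of de novo lipogenesis, which builds fatty acids from acetyl-CoA, rose as a list with estrogen, with a median log2 fold change of 0.88 (1.84-fold) and 18 of 18 tested members positive (camera adjusted p = 3.12e-10; adjusted p = 0.47 with an estimated correlation). Of these, 14 were higher adjusted over the list alone and 0 over all genes, where DESeq2 called 13 higher. Fasn, the fatty acid synthase (ENSMUSG00000025153, chromosome 11, 120805846 to 120824547), had a log2 fold change of 1.05 ± 0.29 (SE). Acly, which makes cytosolic acetyl-CoA, had one of 1.43 ± 0.36, Acacb, an acetyl-CoA carboxylase, 1.61 ± 0.38, and Elovl6, a fatty acid elongase, 1.51 ± 0.36. Genes of triglyceride synthesis and lipolysis also rose as a list (median 0.53, 17 of 18 positive, camera adjusted p = 3.98e-06; adjusted p = 0.47 with an estimated correlation), with 0 members past the threshold either adjusted over the list alone or over all genes (DESeq2 4 higher). Its members of smallest p were Lpin1 (0.69), Agpat2 (0.82), the lipase gene Pnpla2 (0.85) and Mgll (0.44), and without estrogen replicate 3 the median was 0.34 and Pnpla2 was at 0.56.

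The adipocyte identity list rose with a median of 0.45 (16 of 22 positive, camera adjusted p = 0.00940; adjusted p = 0.559 with an estimated correlation), and the call was lost without vehicle replicate 2 (adjusted p = 0.0653), while without estrogen replicate 3 the median was 0.17. Adjusted over the list alone, 1 member was higher, and 0 over all genes (DESeq2 3 higher). Slc2a4, the insulin-responsive glucose transporter, was at 441 ± 94.8 CPM against 242 ± 9.67 CPM, with a log2 fold change of 0.87. The adipokine gene Adipoq had a log2 fold change of 0.63 ± 0.27, Lep -0.73 ± 0.55, and Pparg, the main adipogenic transcription factor, -0.08 ± 0.21. Rbp4 and Nrg4 were at 0.83 and 0.82, and Mest, linked to fat expansion, at -1.27. Without estrogen replicate 3, Adipoq was at 0.31, Lep at -0.28, Rbp4 at 0.53 and Nrg4 at 0.49, while Lep was at -1.11 without estrogen replicate 1.

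Nuclear-encoded OXPHOS subunits, the respiratory chain and ATP synthase, rose as a list, with a median log2 fold change of 0.42 and 74 of 74 positive (camera adjusted p = 4.83e-19; adjusted p = 0.47 with an estimated correlation). Their 39 members at an unadjusted p under 0.05 included Ndufv1 (0.74), Ndufs1 (0.55), Ndufa10 (0.64) and Ndufa6 (0.57), and 0 passed adjusted over the list alone or over all genes (DESeq2 7 higher). Relative to the mean of the 6 libraries, the list lay at 0.0025 in vehicle replicate 1 and at 0.023 in estrogen replicate 1. The list median was 0.32 without estrogen replicate 2 and 0.55 without vehicle replicate 1. Genes encoded on the mitochondrial chromosome had a median of 0.74 (13 of 13 positive, camera adjusted p = 4.46e-06; adjusted p = 0.47 with an estimated correlation), with mt-Nd2 at 0.78 and mt-Nd4 at 0.75, again 0 adjusted over the list alone or over all genes (DESeq2 6 higher). That median was 0.56 without estrogen replicate 3 and 0.91 without vehicle replicate 1. All genes of the mitochondrial chromosome, coding or not, took 8.72, 6.40 and 6.26% of the counts in vehicle replicates 1 to 3. Their share was 9.08, 10.2 and 11.7% in estrogen replicates 1 to 3.

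The TCA cycle list rose (median 0.52, 18 of 18 positive, camera adjusted p = 8.89e-08; adjusted p = 0.47 with an estimated correlation), with 4 members higher adjusted over the list alone and 0 over all genes (DESeq2 4 higher). The 4 members higher adjusted over the list alone were Pcx, the pyruvate carboxylase, and the pyruvate dehydrogenase genes Dlat, Pdha1 and Pdhb. Pcx had a log2 fold change of 0.999 ± 0.25, and Dlat, Pdha1 and Pdhb had 0.81, 0.73 and 0.88. No other member of the list passed that adjustment. Fatty acid oxidation rose as a list (median 0.46, 23 of 24 positive, camera adjusted p = 1.52e-06; adjusted p = 0.47 with an estimated correlation), with 0 members adjusted over the list alone or over all genes (DESeq2 2 higher). Its members of smallest p were Ehhadh (1.10), Eci1 (0.52), Cpt2 (0.54) and Acot2 (0.54). Without estrogen replicate 2 the medians of these lists were 0.34 and 0.29, and Acot2 was at 0.36. Glucose uptake and glycolysis rose (median 0.37, 19 of 22 positive, camera adjusted p = 0.000847; adjusted p = 0.47 with an estimated correlation), with 4 members higher and 1 lower adjusted over the list alone and 0 over all genes (DESeq2 5 higher), and the call was lost without estrogen replicate 2 (adjusted p = 0.0512, median 0.24). Aldoa and Pdk1 had log2 fold changes of 0.87 and 0.76, and Slc2a1, the basal glucose transporter, -0.61. The Aldoa value is for ENSMUSG00000030695, and a second Aldoa entry, ENSMUSG00000114515, was at 2.73 by DESeq2 (adjusted p = 0.0412).

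The thermogenic programme did not pass the test (median 0.43, 20 of 23 positive, camera adjusted p = 0.174). Ucp1, the uncoupling protein that makes heat in brown and beige adipocytes (ENSMUSG00000031710, chromosome 8, 83290352 to 83298452), was at 907, 589 and 333 CPM in vehicle replicates 1 to 3 and at 696, 1754 and 10.2 CPM in estrogen replicates 1 to 3, a log2 fold change of 0.43 ± 1.25 (adjusted p = 0.866). Cidea (0.59 ± 0.50), Dio2 (0.51 ± 0.27), Ppargc1a (0.17 ± 0.21), Prdm16 (-0.09 ± 0.17), Elovl3 (1.21 ± 0.58) and Cox8b (0.20 ± 0.44) did not pass either. The list's member of smallest p was Ppargc1b, a coactivator of mitochondrial genes, at 24.8 ± 4.69 CPM against 12.3 ± 1.22 CPM (log2 fold change 1.005 ± 0.17), the 1 member higher adjusted over the list alone, with 0 over all genes (DESeq2 1 higher). Esrra (0.48), Kcnk3 (0.88) and Pank1 (0.81) followed. At the preset correlation, estrogen replicate 3 decided this list's call, as without it the median was 0.88 and the camera adjusted p 4.00e-07. With all libraries and an estimated correlation the camera adjusted p was 0.787, and no such value without estrogen replicate 3 is given here. Without estrogen replicate 2 the median was -0.23, Ucp1 was at -0.79, Kcnk3 at 0.44, Pank1 at 0.43 and Elovl3 at 0.65.

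**Figure D2:**
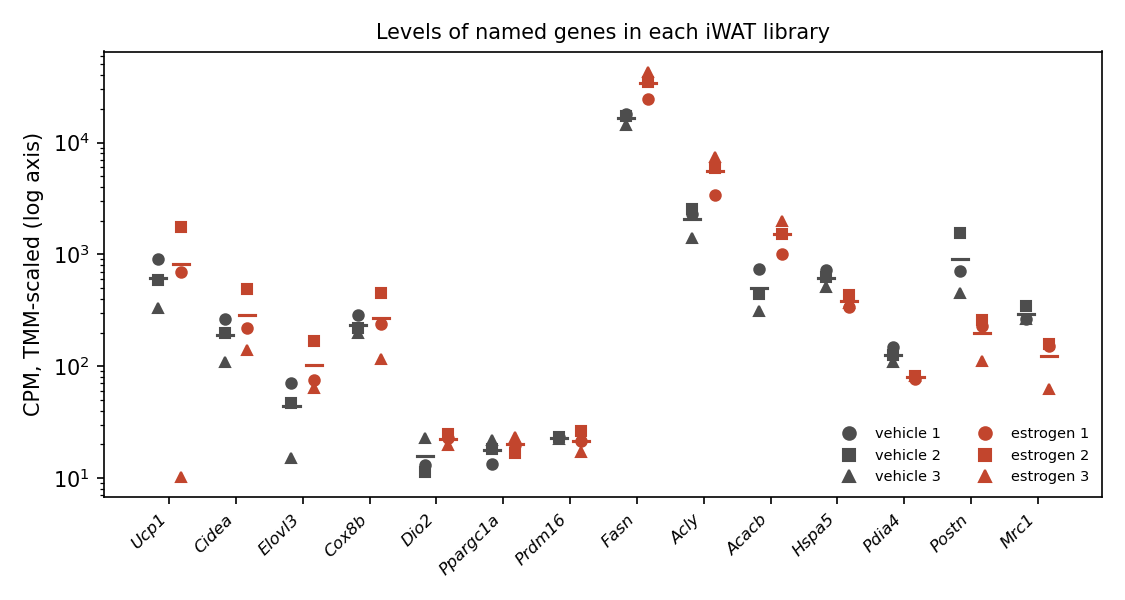
Levels of 14 named genes in each library on a log axis of TMM-scaled CPM, with a horizontal line at the mean of each group and the replicate by symbol. Ucp1 spans 10.2 to 1754 CPM among the estrogen libraries, while Fasn is higher and Hspa5 lower in each estrogen library than in each vehicle library.

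Beige selective markers had a median of -0.0029 (5 of 10 positive, camera adjusted p = 0.809), and the signs of the list's median, mean and test differed. Tbx1 was at 11.3 ± 0.782 CPM against 7.74 ± 0.493 CPM, and Slc36a2, P2rx5 and Ear2 had log2 fold changes of 0.36, 0.49 and -1.29, with Ear2 at -0.66 without vehicle replicate 1 and P2rx5 at 0.23 without estrogen replicate 2. Estrogen receptors and estrogen-responsive genes had a median of 0.01 (8 of 15 positive, camera adjusted p = 0.809), also with differing signs. Esr1, the estrogen receptor alpha, had a log2 fold change of 0.62 ± 0.23 (adjusted p = 0.212) and was at 0.33 without estrogen replicate 3. Rara, Myc and Igf1 had -0.65, -0.45 and -0.25. In both lists 0 members passed adjusted over the list alone or over all genes, nor by DESeq2. The classical estrogen targets Pgr (3, 1 and 1 counts with vehicle, 0 in each estrogen library) and Greb1 (7 counts in all with vehicle and 11 with estrogen) were too low to test, so a response was not detectable at this depth.

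Collagen and matrix remodelling genes fell as a list with estrogen, with a median log2 fold change of -1.56 (2.94-fold lower) and 33 of 33 negative (camera adjusted p = 2.12e-13; adjusted p = 0.47 with an estimated correlation). Adjusted over the list alone 26 were lower, and 0 over all genes, where DESeq2 called 19 lower. Postn, a matrix protein of activated fibroblasts, was at 199 ± 77.9 CPM against 904 ± 570 CPM, and Col8a1, Thbs1 and Acta2 had log2 fold changes of -2.14, -2.30 and -0.85. Adipocyte progenitor markers fell (median -0.98, 16 of 18 negative, camera adjusted p = 0.000112; adjusted p = 0.47 with an estimated correlation), with 2 members lower adjusted over the list alone and 0 over all genes (DESeq2 2 lower). Ly6a was at 147 ± 23.2 CPM against 292 ± 70.5 CPM, and Pdgfra, Clec11a and Dlk1 had log2 fold changes of -0.94, -0.98 and -2.31. Estrogen replicate 3 had the lowest level of both lists, at 1.84 and 1.19 log2 units under the mean of the 6 libraries. Vehicle replicate 2 had the highest, at 1.43 and 1.02 above it. The collagen and progenitor medians were -1.07 and -0.70 without vehicle replicate 2, and -1.18 and -0.84 without estrogen replicate 3. Without vehicle replicate 2, Postn was at -1.56, Col8a1 at -1.49 and Acta2 at -0.59.

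Macrophage markers fell (median -1.01, 18 of 20 negative, camera adjusted p = 8.56e-07; adjusted p = 0.47 with an estimated correlation), with 12 lower and 1 higher adjusted over the list alone and 0 over all genes (DESeq2 3 lower and 1 higher). Mrc1, the mannose receptor of resident macrophages, was at 123 ± 53.1 CPM against 293 ± 46.5 CPM. Itgax and Cd9 had log2 fold changes of -1.69 and -0.99, and Timd4, a marker of long-lived resident macrophages, 1.90. Timd4 was at -0.12 with both estrogen replicates 1 and 3, the libraries high in B cell markers, left out. Inflammatory cytokines and chemokines fell (median -1.02, 22 of 26 negative, camera adjusted p = 0.000212; adjusted p = 0.47 with an estimated correlation), with Tlr2, Il6, Ccl3 and Il1b at -1.60, -2.70, -2.60 and -3.07. The type I interferon response fell (median -0.54, 22 of 23 negative, camera adjusted p = 0.000565; adjusted p = 0.559 with an estimated correlation), with Irf9 at -0.48 and Ifit2 at -0.44. In both lists 0 members passed adjusted over the list alone or over all genes (DESeq2 4 lower among the inflammatory genes and 0 among the interferon genes). Vehicle replicate 1 held the highest levels of both, and of the neutrophil list (1.84 log2 units above the mean of the 6 libraries, against -0.59 to -0.19 in the others), and without it the interferon call was lost (adjusted p = 0.149, median -0.23) and the inflammatory median was -0.64, with Il1b at -1.24 and Ccl3 at -1.53.

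Senescence and secretory factors fell as a list (median -0.50, 13 of 16 negative, camera adjusted p = 0.00556; adjusted p = 0.47 with an estimated correlation), with 1 member lower adjusted over the list alone and 0 over all genes (DESeq2 1 lower). Mmp13, a collagenase, was at 1.15 ± 0.925 CPM against 4.77 ± 3.76 CPM, and the low-level Cdkn2a at 0.386 ± 0.213 against 1.84 ± 2.09 CPM. The median was -0.30 without estrogen replicate 3 and -0.33 without vehicle replicate 2, where Mmp13 was at -1.18 and Cdkn2a at -0.68, against -2.05 and -2.19 with all libraries. Cell cycle genes fell as a list (median -0.90, 30 of 30 negative, camera adjusted p = 4.46e-06; adjusted p = 0.559 with an estimated correlation), with 0 members adjusted over the list alone or over all genes, nor by DESeq2. Pcna and Ube2c had log2 fold changes of -0.46 and -1.33, and without vehicle replicate 1 they were at -0.30 and -0.50. The list median was -0.38 without vehicle replicate 1 and -0.48 without estrogen replicate 3.

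Genes of the unfolded protein response and endoplasmic reticulum chaperones fell as a list (median -0.41, 26 of 33 negative, camera adjusted p = 3.11e-06; adjusted p = 0.47 with an estimated correlation), with 16 lower adjusted over the list alone and 0 over all genes (DESeq2 12 lower). Hspa5, the main chaperone of that compartment, was at 379 ± 48.4 CPM against 619 ± 103 CPM, with a log2 fold change of -0.71 ± 0.18. Sdf2l1, Pdia4, Pdia3 and Creld2 had -1.45, -0.67, -0.69 and -0.93. The stress transcription factors Ddit3 (-0.21 ± 0.22), Atf4 (-0.14 ± 0.13) and Xbp1 (0.13 ± 0.22) did not pass. Heat shock and immediate early genes fell (median -0.996, 17 of 18 negative, camera adjusted p = 4.46e-06; adjusted p = 0.47 with an estimated correlation), with 6 lower adjusted over the list alone and 0 over all genes (DESeq2 7 lower), and Junb, Egr2, Ier3 and Hspa1b at -1.22, -1.50, -1.08 and -1.41. Genes of NAD synthesis and use rose slightly as a list (median 0.16, 17 of 26 positive, camera adjusted p = 0.0268; adjusted p = 0.47 with an estimated correlation), with 0 members adjusted over the list alone or over all genes (DESeq2 1 higher). Nampt, the rate-limiting enzyme of NAD salvage, had a log2 fold change of 0.57 ± 0.18, and the call was lost without vehicle replicate 3 (adjusted p = 0.0537) or estrogen replicate 2 (adjusted p = 0.118). The list median was 0.10 without estrogen replicate 3 and also without vehicle replicate 1.

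Markers of other cell types differed between single libraries. Skeletal muscle markers summed to 12789 CPM in estrogen replicate 1 and to 61.4 to 174 CPM in the other 5 libraries, and the list did not pass (median 6.15, camera adjusted p = 0.0837; median -2.21 without estrogen replicate 1). B cell markers rose as a list (median 3.69, 8 of 8 positive, camera adjusted p = 0.00720; adjusted p = 0.559 with an estimated correlation), with 7 higher adjusted over the list alone and 0 over all genes (DESeq2 7 higher). Without Ighm, they summed to 175 and 126 CPM in estrogen replicates 1 and 3 and to 5.49 to 9.54 CPM in the others. T and NK cell markers rose (median 2.21, 14 of 16 positive, camera adjusted p = 0.000463; adjusted p = 0.559 with an estimated correlation), with 9 higher adjusted over the list alone and 0 over all genes (DESeq2 5 higher), and without estrogen replicate 1 the median was 0.92. Endothelial markers rose slightly (median 0.29, 17 of 18 positive, camera adjusted p = 0.00234; adjusted p = 0.559 with an estimated correlation). Their call was lost without vehicle replicate 1 (adjusted p = 0.0714, median 0.19) or estrogen replicate 3 (adjusted p = 0.0862, median 0.10), and without vehicle replicate 3 the median was 0.47. Erythroid genes rose (median 0.57, 6 of 6 positive, camera adjusted p = 0.00429; adjusted p = 0.559 with an estimated correlation), with medians of 0.33 without estrogen replicate 3 and 0.36 without vehicle replicate 2. In the endothelial and erythroid lists 0 members passed adjusted over the list alone or over all genes, nor by DESeq2.

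**Figure D3:**
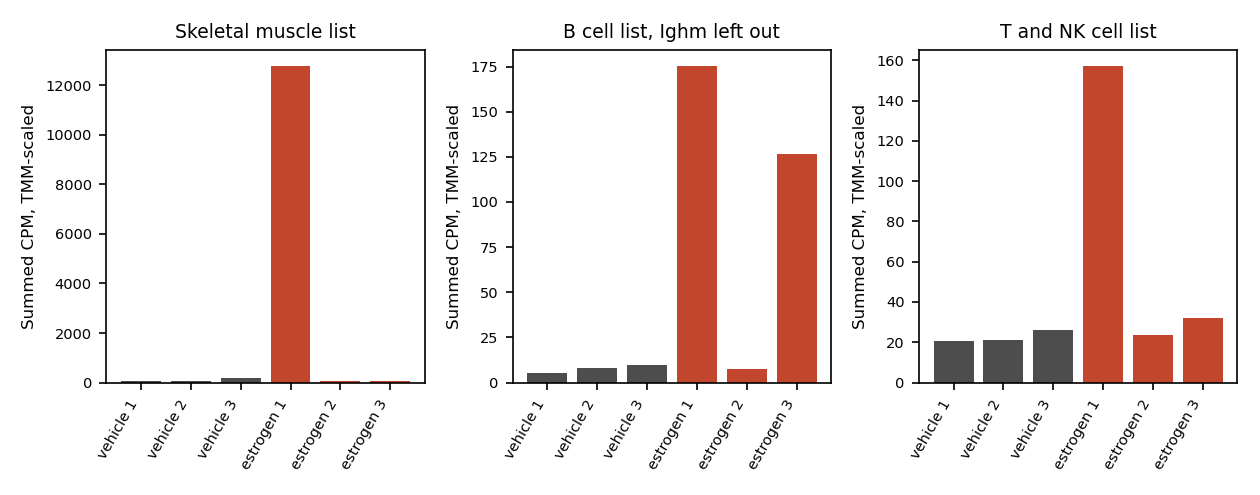
Summed TMM-scaled CPM of the skeletal muscle, B cell (Ighm left out) and T and NK cell lists, as 1 bar per library from 0, with vehicle in grey and estrogen in red. Muscle transcripts stand out in estrogen replicate 1 at 12789 CPM, and B cell transcripts in estrogen replicates 1 and 3 at 175 and 126 CPM.

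The other lists were not called. Median log2 fold changes were 0.34 for the circadian clock (camera adjusted p = 0.0681), 0.23 for adrenergic and cAMP signalling (0.0693), 0.20 for cholesterol synthesis (0.132), -0.95 for neutrophils (0.151) and -0.09 for creatine and calcium cycling (0.401). Mammary epithelium was at -0.11, Schwann cells and nerve at 0.10, plasma cells at 0.32, mast cells and eosinophils at 0.10, smooth muscle and pericytes at 0.14, lymphatic endothelium at 0.64 and dendritic cells at -0.08, with camera adjusted p from 0.401 to 0.828. Signs of the median, mean and test differed for creatine and calcium cycling, mammary epithelium, mast cells and eosinophils, and dendritic cells. Without estrogen replicate 2 the clock list was called (adjusted p = 0.000617, median 0.65), while without estrogen replicate 3 its median was 0.14 (adjusted p = 0.219), and adrenergic signalling, skeletal muscle, cholesterol synthesis and neutrophils were each called in 2 or 3 of the 6 fits that left out 1 library. The cholesterol median was 0.030 without estrogen replicate 2, 0.036 without vehicle replicate 3 and 0.36 without vehicle replicate 1, and the creatine and calcium cycling median ran from -0.30 to -0.060 over these fits. Single libraries also set the direction of several medians. Without vehicle replicate 1 the neutrophil median was 0.24 (adjusted p = 0.907), against -1.43 without vehicle replicate 2 and -1.39 without vehicle replicate 3. Without estrogen replicate 1 the medians were -0.59 for lymphatic endothelium, -0.055 for mast cells and eosinophils and -0.047 for smooth muscle and pericytes, and mast cells and eosinophils were at -0.016 without estrogen replicate 2. Schwann cells and nerve were at -0.045 without estrogen replicate 3, where plasma cells were at 0.012. The highest medians in such fits were 0.33 for Schwann cells and nerve, 0.97 for plasma cells, 0.38 for mast cells and eosinophils and 0.28 for smooth muscle and pericytes. The mammary median was negative in each of these fits, between -1.50 and -0.054. The dendritic median ran from -0.35 to 0.085 over the fits that left out 1 library. Lists of skin, mesothelium and sex-linked genes had 3 or 4 tested members and were not tested.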

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

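Robust dispersions, library quality weights and leaving out both estrogen replicates 1 and 3 were chosen only after the data were seen, as was the choice to print here where the median of the thermogenic, beige or estrogen-responsive list changed sign. Genes past the threshold stayed at 0 in both directions under each scaling and filter alternative, limma-voom, robust dispersions and quality weights, with 2926 to 4048 genes at an unadjusted p under 0.05. The fold threshold and the looser threshold of 0.1 were applied to the main edgeR fit. Its smallest adjusted p was 0.207, so both could only give 0. The number of genes at an unadjusted p under 0.05 was 1459 to 3239 when each library was left out. The exceptions were 384 higher and 460 lower with DESeq2 (960 genes had no adjusted p), 0 to 13 higher when each library was left out in turn, and 1 higher with both estrogen replicates 1 and 3 left out. That gene was the immunoglobulin gene Ighg2b, and the 1 remaining estrogen library was then assumed to vary like the vehicle libraries. The cause of the difference between DESeq2 and edgeR was not tested. Lists called fell from 22 to 0 with an estimated correlation and to 0 with fry. They numbered 21 to 26 under all other settings, 21 to 25 when each library was left out, and 17 of the 22 calls were kept in every one of those fits.

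With the replicate number as a block, 0 genes were higher and 0 lower (smallest adjusted p = 0.0594), 26 lists were called, Ucp1 was at -0.92 and Cox8b at -0.00051. Deviations of same-numbered samples correlated at -0.13, 0.14 and 0.28, and not all exceed 0.1, so the samples were taken to share only a number, and not every sample correlated best with its own number. The deposited columns carry other numbers, 1, 3 and 4 for vehicle and 1, 2 and 4 for estrogen, in the order of the title numbers. Only 1 and 4 are then shared, and they match title numbers 1 and 3 (-0.13 and 0.28), and whether any number marks a pair stays unknown. With limma-voom, Ucp1 was at -1.34 and Cox8b at -0.0025. With both estrogen replicates 1 and 3 left out, log2 fold changes were -0.083 for Ppargc1a, 0.21 for Prdm16, 0.22 for Ddit3, 0.014 for Atf4, -0.16 for Xbp1 and -0.12 for Timd4, and the estrogen-responsive list's median was -0.12. With quality weights, Xbp1 was at -0.0059 and that list at -0.083. The beige list's median was 0.0063 with RLE factors and 0.040 with upper-quartile factors. When each library was left out in turn, log2 fold changes ran from -0.79 to 1.02 for Ucp1, -0.072 to 0.93 for Cidea, -0.25 to 0.056 for Prdm16, -0.40 to 0.57 for Cox8b, 0.32 to 0.87 for Dio2, 0.00073 to 0.33 for Ppargc1a, 0.65 to 1.72 for Elovl3, -0.47 to -0.058 for Ddit3, -0.22 to -0.071 for Atf4, -0.29 to 0.072 for Pparg and -0.13 to 0.25 for Xbp1. Medians ran from -0.23 to 0.88 for the thermogenic list, -0.21 to 0.17 for the beige list and -0.14 to 0.080 for the estrogen-responsive list. The cause was not tested for any of these. Median log2 fold changes of all genes were 0.0025, 0.01 and 0.04 under TMM, RLE and upper-quartile scaling. At this depth and number of libraries, most changes of 2-fold were missed on simulated data.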

Other observations

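The tests below were chosen only after the results were seen, except the count of lists called in other splits of the libraries. Genes that the rule did not name are named here after their values were seen, and none passed the threshold (edgeR adjusted p of 0.207 or more). Of the cytosolic ribosomal protein genes, 75 of 81 were negative (median log2 fold change -0.21), and of the mitochondrial ribosomal protein genes 70 of 77 were positive (median 0.28). Neither family was tested as a list. Prlr, the prolactin receptor, was at 7.99 ± 1.69 CPM with estrogen against 4.0 ± 0.781 CPM with vehicle (SD, n = 3), beside Oxtr, another hormone receptor. Both belong to the mammary epithelium list, where 2 members were higher adjusted over the list alone and 0 over all genes (DESeq2 2 higher). Krt8, Krt18, Epcam and Csn2 of that list had 0 to 4 counts per library and were too low to test. The values of Oxtr and Prlr thus cannot be assigned to mammary epithelium. In estrogen replicate 3, the clock-controlled gene Dbp was at 128 CPM against 21.7 to 64.1 CPM in the other 5 libraries and the core clock gene Arntl at 2.99 CPM against 9.74 to 25.6 CPM. Per1 was higher in each estrogen library than in each vehicle library, with a log2 fold change of 1.51. Immunoglobulin genes were positive in 18 of 20 cases, 3 of them at an unadjusted p under 0.05 (edgeR). Relative to the mean of the 6 libraries, their level was 1.05 and 1.635 in estrogen replicates 1 and 3. In estrogen replicate 2 it was -0.455, within the vehicle range of -1.93 to 0.199. Ighg2b was at 10.4, 58.9 and 7.66 CPM in estrogen replicates 1 to 3 and at 0.610, 0.708 and 1.13 CPM in vehicle replicates 1 to 3. Gapdh ranged from 11.5 to 280 CPM, but it has many pseudogene copies and its count is uncertain. The Y-linked genes Ddx3y and Eif2s3y were present in all 6 libraries, at 69.9 to 115 CPM and 66.3 to 84.2 CPM, and Xist had 0 to 6 counts. The labels do not state the sex of the mice, and these values argue against female mice in any of the 6 libraries.

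With 3 samples against 3 there are 10 splits of the libraries, too few for a share under 0.05. The real split gave 0 genes higher and 0 lower, as many as all 10 splits (highest other 0), and a count of 0 is matched by any split. It gave 22 lists, as many as 1 of the 10 splits, the real one, with 20 as the highest other. It gave 3185 genes at an unadjusted p under 0.05, again matched by 1 split, the real one, with 1101 as the highest other.

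For the gap between the lipogenesis and collagen medians (2.44 log2 units), which belongs to a joint rise of lipid and mitochondrial lists and fall of matrix, macrophage, progenitor and inflammatory lists, a trend with GC content or transcript length is argued against, as the trend was weak (Spearman 0.023 and -0.11 across genes) and spanned 0.0972 of the gap, and at most 0.143 in fits that left out 1 library. A lower share of all non-adipocyte cells would lower the markers of each other cell type alike. Endothelial, smooth muscle and Schwann cell levels differed by 0.289, 0.127 and 0.0732 log2 units, estrogen minus vehicle, with SDs of 0.064 to 0.285 within groups. These values argue against an even fall in those cell types as large as the macrophage median of -1.01. Neutrophil (-0.95), mammary (-0.11) and dendritic (-0.08) medians were negative. A smaller even fall cannot be told apart. The endothelial level lay above the macrophage level by 1.29 log2 units more with estrogen, but with a 95% t interval over libraries of -0.431 to 3.0. Without estrogen replicate 3, which had the lowest matrix and macrophage levels, the 11 lists kept 0.631 to 1.42 of their medians and all stayed called with the preset correlation (largest adjusted p = 0.000419), but none with an estimated one (smallest adjusted p = 0.491). An estimated correlation called 0 lists with all 6 libraries too, so that loss does not single out estrogen replicate 3. Both other estrogen libraries lay beyond all vehicle libraries in 11 of 11 lists. The chance is 10% per list for a direction fixed in advance, but lists and directions were taken from these same libraries. The lists are also not independent of each other, so this count is no separate support. Most of each median was left without estrogen replicate 3. Whether what was left exceeds the spread cannot be told with so few libraries. The 95% t interval over the other 5 libraries left out 0 for 1 of the 11 lists, the macrophages (-1.07 to -0.094). A fall in matrix, macrophage and progenitor cells themselves, changed expression within cells, and the estrogen treatment stay open and untested.

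Skeletal muscle transcripts in estrogen replicate 1 may come from muscle tissue taken along with the fat pad. Of 17 tested muscle markers, 15 reached at least 10 times the highest of the other 5 libraries there, with Acta1 at 1636 CPM, Ttn at 829 CPM and Ckm at 648 CPM. Muscle-like genes of brown or beige adipocytes are argued against, as the library with the most Ucp1, estrogen replicate 2, held 0.00171 of the median muscle marker level of estrogen replicate 1. An effect of estrogen was not tested.

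B cell transcripts were high in estrogen replicates 1 and 3 and might come from lymph node tissue, which lies within this fat pad. The ratio of T to B cell counts was 0.896 in estrogen replicate 1 (95% exact binomial interval 0.853 to 0.942) and 0.253 in estrogen replicate 3 (0.228 to 0.281), a 3.54-fold difference. The intervals cover counting error only, and the spread between samples of lymph node is not known here, so the ratios do not decide on the make-up. Lymph node tissue, lymphocytes within the fat and an effect of estrogen stay open and untested.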
